A study of Rattus norvegicus with 9 samples.

How the data were processed

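Poly-A selected RNA from rat endometrium was sequenced in 9 libraries, 3 in each of the groups NER, LER and LER+LIG, with the groups and replicate numbers taken from the sample titles. The series abbreviates its group names, and only the treatments behind them were used here. The authors' deposited expression table gives 1 row per gene with Ensembl rat identifiers and symbols, and holds read counts per gene and library as whole numbers, per the file headers. The same deposited table gives FPKM, and in the 17844 rows with counts these equalled the count divided by 1 gene length and the library's count total, to a largest relative difference of 7.5e-15. The FPKM of the authors were used only to recover those gene lengths, which covered all 14232 tested genes and had a median of 2726 bases. The authors' deposited table of comparisons holds a log2 fold change, an unadjusted p-value and a call for LER against NER and for LER+LIG against LER. Its calls matched an absolute log2 fold change of at least 1 with p under 0.05 in all 13995 rows. The aligner, the counter, the genome build and the test behind that table are not given in the sources used here.

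Total counts were 13241537 to 15354085 per library over 22250 rows. The 10 most abundant genes took 7.43% to 9.15% of the counts, mitochondrially encoded genes took 2.14% to 5.46%, and rows without a symbol took at most 0.0031%. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes could not be separated, and near-identical copies such as RT1 and globin genes may share reads. No pair of libraries agreed within sampling noise: chi-square per degree of freedom was 18.8 or more for every pair. No batch or date was given in the labels.

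Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups, libraries were scaled by TMM with factors of 0.867 to 1.05, dispersions were estimated over all 9 libraries, and glmQLFit with robust estimation was followed by glmQLFTest for LER minus NER, LER+LIG minus LER and LER+LIG minus NER. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. Standard errors of log2 fold changes were taken as the fold change divided by the root of the F statistic. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 48 lists that had at least 5 tested members. The same lists were tested with an estimated correlation and with fry, whose directional p asks whether a list's genes move one way on balance. The 49 lists, 28 of processes, 19 of cell type markers and 2 of RNA quality, were written before the data were examined, as were the groups, the tests, the alternative settings and the rule for named genes. Of 1090 list entries, 1037 matched by symbol, 10 by an older symbol in the RefSeq table of assembly GRCr8, and 43 had no match. That table was used for names only, and coordinates are not reported because the authors' build is unknown. Where rows shared a symbol, the row with the most counts was used.

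Named genes followed 1 rule. The 8 called genes with the largest fold in each direction, or 4 for LER+LIG against NER, were to be named if their groups did not overlap and their mean over the 9 libraries was at least 2 CPM. Where none was called, the 3 with the smallest p in each direction were named as not called. Up to 4 members with the smallest p were open to naming for each list that passed, and 13 receptivity, hormone receptor and cell cycle genes were always named. Genes called in both contrasts with opposite signs would also have been named, and there were none by edgeR.

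The procedure was tested on simulated counts drawn from the real means, library sizes and dispersions with 200 changed genes. Of genes changed by a log2 fold of 1, 2 and 3, edgeR called 2.99%, 46.3% and 72.7% for LER against NER, and 2.99%, 38.8% and 75.8% for LER+LIG against LER, among 14057 and 14052 genes tested, with 9 and 3 calls of unchanged genes. A simulated list shifted by 1 was called in both contrasts, with 0 of the 47 unshifted lists. Genes were drawn independently of each other, so this result does not cover false calls of lists whose genes vary together. With dispersions multiplied by 0.1 edgeR called 79.1%, 89.6% and 97.0% for LER against NER among 14070 genes, and 85.1%, 95.5% and 97.0% for LER+LIG against LER among 14073, with 9 and 8 calls of unchanged genes and the same result for the lists. Library sizes were not varied.

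The alternative settings for counts were DESeq2 size factors, upper-quartile scaling, the DESeq2 1.42.0 Wald test, no filter, fits of only the 2 groups compared, the replicate number as a block, other thresholds and leaving out each library. Added after seeing the data were a covariate for the difference of the oestrogen and progesterone list means and an offset that removed each library's trend with gene length, a lowess curve with a span of 0.3. Other splits of the libraries, a simulation of unchanged groups sharing the LER libraries, with the authors' thresholds applied to it after seeing the data, and 10000 random lists matched on expression were also computed.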

Results

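Endometrial messenger RNA was sequenced from female Sprague-Dawley rats, 10 weeks old, in 3 groups of 3 libraries. The group labelled NER received saline before mating and olive oil afterwards. The group labelled LER received hydroxyurea, which blocks the supply of deoxynucleotides, by gavage at 450 mg/kg daily for 10 days. It also received adrenaline under the skin at 0.3 mg/kg daily from day 4 to day 10, and olive oil after mating. The LER+LIG group had the same 2 drugs and then LIG, ligustilide per the series title, by gavage at 40 mg/kg daily from day 0.5 of gestation. The day of tissue collection was not given in the sources used here. Total counts per library lay between 13241537 and 15354085 over 22250 gene rows, and 14232 genes had enough counts to be tested. Nothing in the labels says whether each library came from a separate animal, so the p-values measure the spread between these libraries.

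The largest difference among the 9 libraries did not follow the 3 groups. The first principal component of log2 normalised counts (CPM, scaled to library size) held 44.4% of the variance and placed NER replicate 3 at 84.5, LER+LIG replicate 2 at 71.3 and LER+LIG replicate 3 at 74.0. The other NER and LER libraries lay between -37.5 and -28.7, and LER+LIG replicate 1 lay at -68.1. Across genes, NER replicate 3 correlated with LER+LIG replicate 3 at r = 0.952, and with NER replicates 1 and 2 at r = 0.879 and r = 0.885. The 5 libraries made up of LER and NER replicates 1 and 2 correlated with each other at r = 0.963 to r = 0.977. Genes are not independent replicates, so these values describe the libraries and carry no p-value.

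**Figure D1:**
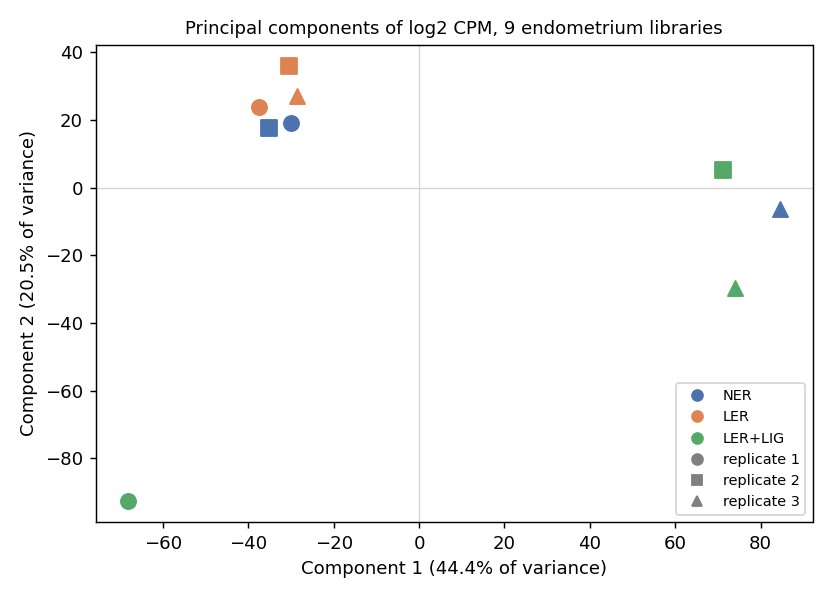
Each point is 1 library placed by the first 2 principal components of log2 CPM over 14232 genes, with the percent of variance on each axis, colour for the group and shape for the replicate number. NER replicate 3 lies at 84.5 on the first component beside LER+LIG replicates 2 and 3, and LER+LIG replicate 1 lies apart at -68.1.

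The comparison of LER with NER asks what hydroxyurea and adrenaline before mating left in the endometrium. Markers of natural killer cells fell in LER: all 14 tested members were lower, with a median log2 fold change of -0.92. The list passed camera at a Benjamini-Hochberg adjusted p of 2.42e-13, and had adjusted p = 0.33 with an estimated correlation and 0.98 by fry. Every other split of these 6 libraries passed more lists by camera than the real one, so a pass alone does not set LER apart from NER. Ncr1, an activating receptor of natural killer cells, was at 0.73 ± 0.29 CPM in LER and 2.09 ± 0.17 CPM in NER (SD, n = 3 each), and the 3 libraries of each group did not overlap. Its LER libraries were at 0.75, 1.00 and 0.43 CPM, near the floor, so its fold change rests on few reads. Prf1, which encodes perforin, was at 11.1 ± 2.9 CPM against 22.4 ± 12.4 CPM, and Nkg7 at 7.41 ± 2.12 CPM against 15.6 ± 6.7 CPM. In 6 of the 14 members the groups did not overlap. The list was called with each of the 9 libraries left out in turn, but NER replicate 3 set much of its size. Without that library the list median was -0.39, Prf1 had a log2 fold change of -0.46 in place of -1.01 and Nkg7 -0.67 in place of -1.07, while Ncr1 had -1.56. None of its members was called alone, with 0 by edgeR adjusted over the list alone, and 0 over all genes by edgeR and by DESeq2.

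Inflammatory cytokines and chemokines under NF-kB control also fell in LER, with 18 of 19 members lower and a median log2 fold change of -0.53 (camera, adjusted p = 6.15e-07; adjusted p = 0.33 with an estimated correlation). Il1b, the interleukin-1 beta gene, was at 5.27 ± 0.50 CPM in LER and 10.2 ± 3.6 CPM in NER (SD, n = 3 each). Il18 was at 4.00 ± 0.33 CPM against 7.44 ± 3.68 CPM, and Ccl4 at 1.12 ± 0.16 CPM against 2.96 ± 1.87 CPM. This list was called with each of the 9 libraries left out in turn, with a median of -0.85 without NER replicate 1. Without NER replicate 3 the log2 fold change was -0.41 in place of -0.89 for Il18, -0.76 in place of -1.39 for Ccl4 and -0.65 in place of -0.96 for Il1b. For this list 0 of the members passed by edgeR adjusted over the list alone, and 0 over all genes by edgeR and by DESeq2.

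8 further lists fell by the same test and rested on fewer libraries. With an estimated correlation these 8 had adjusted p from 0.33 for neutrophils to 0.80 for mitochondrially encoded genes. Cholesterol synthesis was lower in all 22 members, by a median of -0.56. Interferon-stimulated genes were lower in 26 of 29, MHC class II genes in 11 of 12, integrins and adhesion molecules in 24 of 25, T cell markers in 16 of 18, macrophage and dendritic cell markers in 19 of 21, and neutrophil markers in 8 of 9. NER replicate 3 was the highest NER library on these 7 lists. Its list medians relative to LER were 1.23 for cholesterol synthesis, 1.79 for MHC class II, 1.602 for T cells and 1.36 for macrophages, while NER replicates 1 and 2 lay between -0.28 and 0.22 on these 4 lists. On interferon-stimulated genes, integrins and neutrophils it was at 0.97, 0.699 and 0.57, and the higher of NER replicates 1 and 2 at 0.28, 0.28 and 0.47. Without that library camera gave adjusted p = 0.61 for cholesterol synthesis, 0.29 for interferon-stimulated genes, 0.14 for integrins and 0.091 for neutrophils, with medians of -0.04, -0.11, -0.16 and -0.45. Without it the direction turned for MHC class II at 0.84, T cells at 0.84 and macrophages at 0.070. The macrophage call was also lost without LER replicate 2 at adjusted p = 0.14, and the neutrophil call without LER replicates 2 or 3 at 0.25 and 0.35 and without the low-count filter at 0.31. The neutrophil median of -0.68 became -0.21 without NER replicate 2, -0.28 without LER replicate 2, -0.38 without LER+LIG replicate 2 and -1.47 without LER replicate 1, and the interferon median of -0.43 became -0.66 without LER replicate 1. Mitochondrially encoded genes were lower in all 12 members by a median of -0.28, and turned without NER replicate 1 at adjusted p = 0.78 and without LER replicate 1 at 0.95. Their median was -0.46 without NER replicate 3 and -0.496 without LER replicate 3.

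4 lists rose in LER by the same test. With an estimated correlation they had adjusted p from 0.57 for adipocytes to 0.63, so 0 of the 14 called lists held. Progesterone-responsive uterine genes were higher in 17 of 21 members by a median of 0.34, among them Sox17, a transcription factor gene of epithelium and endothelium, at 280.4 ± 81.3 CPM in LER and 165.3 ± 45.8 CPM in NER (SD, n = 3 each). Genes of Wnt, BMP and Hedgehog signalling were higher in 19 of 30. Without NER replicate 3 camera gave these lists adjusted p = 0.70 and 0.98 with medians of 0.02 and 0.03, and without LER replicate 2 it gave 0.14 for the signalling list with 0.13. The progesterone median was 0.62 without NER replicate 2 and 0.22 without LER replicate 3. Adipocyte markers were higher in all 13 members by a median of 2.48, which came from LER replicate 1 at a list median of 2.44 against -1.12 and -1.18 in LER replicates 2 and 3. Cidec, a lipid droplet gene, was at 61.7 CPM in that library and 2.54 and 1.07 CPM in the others. The direction turned without LER replicate 1, to a median of -0.37 at adjusted p = 0.74. Erythroid genes were higher in 7 of 10, with Hba-a1, an alpha globin gene whose near-identical copies can share reads, at 1245 CPM in LER replicate 1 and 241 and 296 CPM in the others. The erythroid call was lost without LER replicate 1 at adjusted p = 0.72, with a median of 0.19, and without NER replicate 2 at 0.14.

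No single gene was called between LER and NER. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14232 genes, with a smallest adjusted p of 1.00. At an unadjusted p under 0.05 it had 124 genes, 39 higher and 85 lower, where 711.6 were expected by chance. DESeq2 called 2 genes, both lower. In 821 of 12142 genes above the mean minimum (6.76%) the groups did not overlap, where chance gives 10%. The smallest p among those that did not overlap belonged upward to Nxpe5, at 28.9 ± 14.0 CPM in LER and 8.73 ± 2.03 CPM in NER (SD, n = 3 each), Gpr27, a G-protein-coupled receptor gene, and Matn4, a matrix protein gene. Downward they belonged to Map2k3, a kinase gene of the p38 pathway, at 2.79 ± 1.62 CPM against 8.44 ± 2.05 CPM, Slc9a4 and Il1b. The log2 fold changes of the 6 genes lay between -5.34 for Slc9a4 and 2.69 for Gpr27, and Slc9a4 was at 14.0 CPM in NER replicate 3 and under 0.70 CPM in the other NER libraries.

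**Figure D2:**
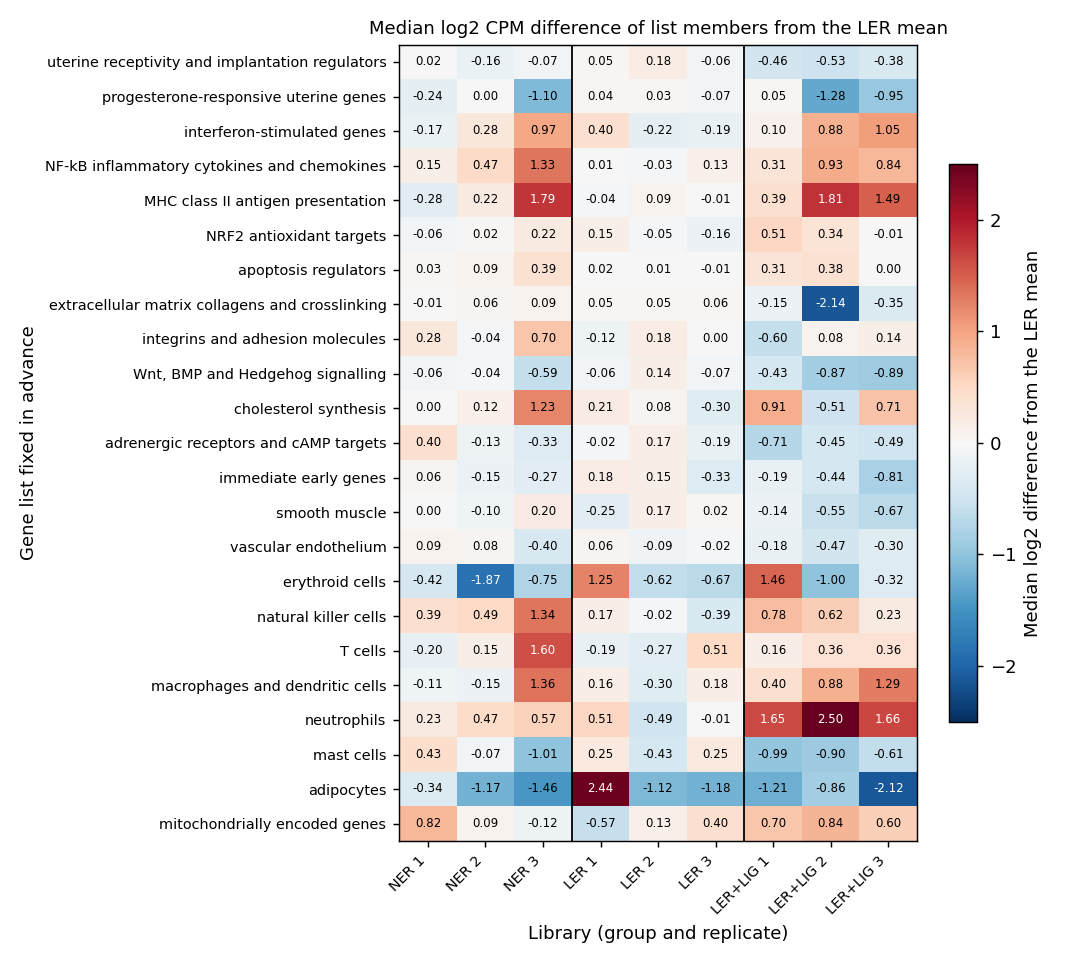
Each cell is the median, over the tested members of a list fixed before the data were examined, of the difference in log2 CPM from the LER mean in 1 library. Rows are the lists called in either comparison, and the values run from 2.499 for neutrophil markers in LER+LIG replicate 2 to -2.14 for collagens in the same library.

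Genes of uterine receptivity were not called between LER and NER by edgeR. Lif, the cytokine needed for implantation in rodents, was at 15.4 ± 4.2 CPM in LER and 15.2 ± 3.4 CPM in NER (SD, n = 3 each). Itgb3 and Itgav, the integrin subunits of the embryo attachment receptor, were at 34.2 ± 8.6 CPM against 46.2 ± 13.5 CPM and at 87.8 ± 10.8 CPM against 106.0 ± 32.0 CPM. The hormone receptor genes Esr1 and Pgr had log2 fold changes of -0.14 ± 0.30 and -0.46 ± 0.75 (SE). Ihh, a progesterone-induced epithelial ligand gene, was at 2.97 CPM in NER replicate 3 and at 30.6 and 74.7 CPM in the other NER libraries. Muc1, a surface mucin gene, was at 64.7 CPM in NER replicate 3 and between 7.94 and 12.5 CPM in the other NER and the LER libraries. Vegfa, Hoxa11 and the cell cycle genes Mki67, Rrm2 and Cdkn1a had log2 fold changes of 0.47 ± 0.36, 0.82 ± 0.76, -0.14 ± 0.59, -0.03 ± 0.74 and -1.13 ± 0.66 (SE). Without NER replicate 3 Pgr, Ihh and Cdkn1a changed sign, to 0.31, -0.17 and 0.13, and without LER replicate 3 Hoxa11 did, to -0.07. Mki67 and Rrm2 changed sign without NER replicates 1 or 2 or LER replicates 1 or 2, reaching 0.12 and 0.20, and Lif without NER replicate 2 or LER replicate 1, reaching -0.23. With 1 library left out Itgb3 ranged from -0.66 to -0.17, Itgav from -0.43 to -0.0034, Esr1 from -0.28 to -0.042 and Vegfa from 0.24 to 0.69. Hoxa10 had 0 or 1 count per library and was not tested. The adjusted p of these genes was 1.00 by edgeR.

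**Figure D3:**
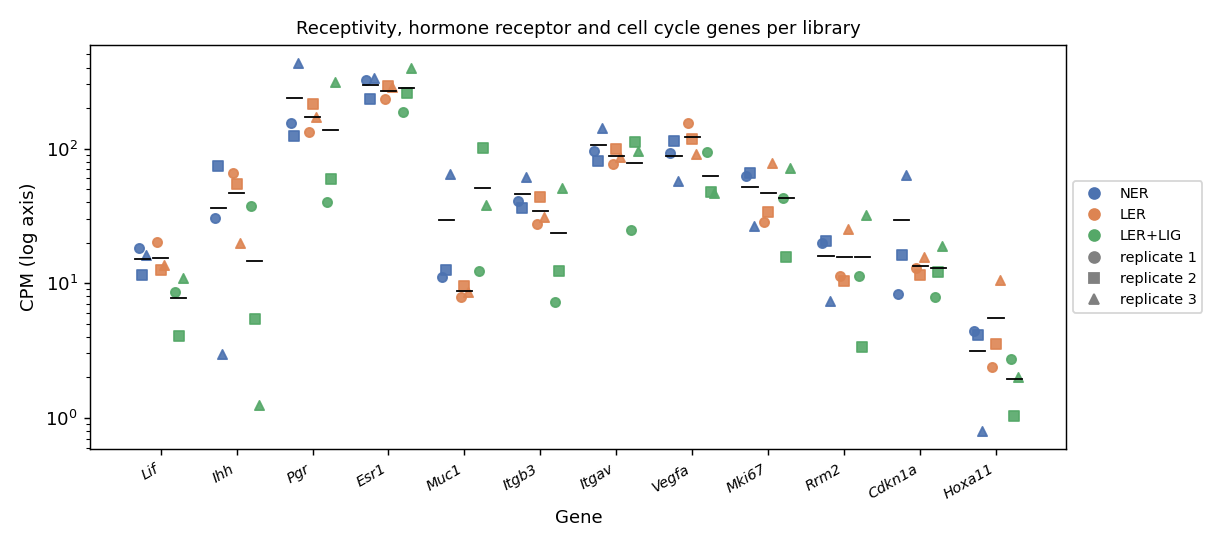
Points are single libraries in CPM on a log axis for 12 genes named in advance, coloured by group and shaped by replicate number, with a black bar at the mean of the 3 libraries. NER replicate 3 and LER+LIG replicates 2 and 3 are low for Ihh, at 2.97, 5.38 and 1.24 CPM, and high for Muc1, at 64.7, 102 and 37.8 CPM.

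The comparison of LER+LIG with LER asks what ligustilide changed in the drug-treated rats. Markers of neutrophils rose, with all 9 tested members higher and a median log2 fold change of 2.07. The list passed camera at adjusted p = 1.91e-05, and had adjusted p = 0.19 with an estimated correlation. The list median lay at 1.65, 2.499 and 1.66 above the LER mean in the 3 LER+LIG libraries, and between -0.49 and 0.57 in the other 6. Cxcr2, a chemokine receptor gene of neutrophils, was at 4.42 ± 1.54 CPM in LER+LIG and 1.04 ± 0.46 CPM in LER (SD, n = 3 each). Lcn2, which encodes a siderophore-binding protein also made by epithelium, was at 35.7, 490.3 and 108.4 CPM against 11.6 ± 3.6 CPM. By edgeR 4 of the 9 members passed adjusted over the list alone and 0 over all genes, while DESeq2 called 3 over all genes, Cxcr2, Lcn2 and Csf3r.

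Other immune and inflammatory lists rose with it. camera gave adjusted p of 1.20e-05 for interferon-stimulated genes, 8.82e-05 for MHC class II, 0.0035 for NF-kB genes, 0.00027 for macrophages and 0.0082 for natural killer cells, and adjusted p = 0.48 with an estimated correlation for each of the 5. Interferon-stimulated genes were higher in 28 of 29 members by a median of 0.71, with Ifi44 at 75.5 ± 9.0 CPM against 35.8 ± 10.8 CPM and 0 members passing adjusted over the list alone. MHC class II genes were higher in 10 of 12 by 1.24, with RT1-Ba at 212.9 ± 179.9 CPM against 16.9 ± 6.9 CPM and 2 passing adjusted over the list alone. RT1-Bb, the partner of RT1-Ba, was at 142.8 ± 120.0 CPM against 31.1 ± 23.4 CPM. The ratio of RT1-Ba to RT1-Bb set LER+LIG apart, so RT1-Ba may carry a haplotype effect, weighed below. NF-kB cytokines and chemokines were higher in 15 of 19 by 1.13, with Il1b at 14.7 ± 2.4 CPM against 5.27 ± 0.50 CPM and 4 passing adjusted over the list alone. Macrophage and dendritic cell markers were higher in 19 of 21 by 1.05, with Fcer1g, an Fc receptor chain gene, at 118.2 ± 35.8 CPM against 33.2 ± 7.2 CPM, while the scavenger receptor gene Cd163 was lower at 7.396 ± 3.814 CPM against 19.99 ± 11.21 CPM, a log2 fold change of -1.96 to -0.92 with 1 library left out. Natural killer cell markers were higher in 13 of 14 by 0.66, with Ncr1 at 2.89 ± 0.38 CPM against 0.73 ± 0.29 CPM, and 1 passed adjusted over the list alone. Over all genes edgeR called 0 members of these lists, while DESeq2 called Ifi44, Ifit3, RT1-Ba, RT1-Db1, Il1b, Il18, Cxcl6 and Ncr1. The natural killer call was lost without LER+LIG replicate 1, at adjusted p = 0.055. On 4 of these lists LER+LIG replicate 1 lay nearer to LER than replicates 2 and 3 did: its medians were 0.10 for interferon-stimulated genes, 0.39 for MHC class II, 0.31 for NF-kB genes and 0.40 for macrophages. On the same 4 lists NER replicate 3, which had no ligustilide, was at 0.97, 1.79, 1.33 and 1.36. On the natural killer list it was at 1.34, above the 3 LER+LIG libraries at 0.78, 0.62 and 0.23. NER replicates 1 and 2 were at 0.39 and 0.49 on that list. The interferon median was 1.08 without LER+LIG replicate 1 and 0.42 without LER+LIG replicate 3, and the NF-kB median was 0.74 without LER+LIG replicate 2 and 0.73 without LER+LIG replicate 3. A covariate for the difference of the oestrogen and progesterone list means was chosen after seeing the data. With it camera called none of the 5, at adjusted p of 0.51, 0.31, 0.21, 0.57 and 0.26 in the order named. This score was 2.78 in NER replicate 3, 1.80 and 2.32 in LER+LIG replicates 2 and 3, and -1.29 to -0.92 in the other libraries. It marks LER+LIG replicates 2 and 3 themselves, so the lost calls do not tell hormone response from ligustilide.

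3 more lists rose. camera gave adjusted p of 0.012 for NRF2 targets, 0.038 for apoptosis regulators and 0.00028 for mitochondrially encoded genes, and adjusted p = 0.48 with an estimated correlation for each. NRF2 antioxidant targets were higher in 19 of 24 by a median of 0.39, among them Prdx1, a peroxiredoxin gene, at 526.4 ± 187.3 CPM in LER+LIG and 272.9 ± 25.5 CPM in LER (SD, n = 3 each), a log2 fold change of 0.59 to 1.10 with 1 library left out. Apoptosis regulators were higher in 16 of 23 by 0.27, among them Casp1, the inflammatory caspase gene, at 55.0 ± 19.7 CPM against 21.9 ± 2.1 CPM. The protective genes Birc3 and Bcl2l1 of that list had log2 fold changes of 2.96 and -0.68, and that of Birc3 was 0.93 without LER+LIG replicate 2, where it stood at 110.3 CPM against 7.98 and 13.9 CPM in replicates 1 and 3. Mitochondrially encoded genes, a list of RNA quality, were higher in 11 of 12 by 0.69. The list lay at 0.70, 0.84 and 0.60 from the LER mean in LER+LIG. NER replicate 1, which had no ligustilide, was at 0.82, and LER replicate 1 was at -0.57. In LER+LIG replicates 1 to 3 the NRF2 list lay at 0.51, 0.34 and -0.0054 from the LER mean. The apoptosis list lay at 0.31, 0.38 and 0.0048, so replicate 3 showed no rise on either list. The NRF2 call was lost without LER replicate 3 at adjusted p = 0.091 and without LER+LIG replicate 1 at 0.15, with a median of 0.18. The apoptosis call was lost without LER replicates 1 or 2 at 0.054 and 0.051, and without LER+LIG replicates 1 or 2 at 0.15 and 0.056, and its median was 0.43 without LER replicate 3. The mitochondrial median was 0.42 without LER replicate 1.

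Collagens and their crosslinking enzymes fell in LER+LIG, with 20 of 23 members lower and a median log2 fold change of -0.60. camera gave the list adjusted p = 2.92e-06, and adjusted p = 0.48 with an estimated correlation. Col4a2, a basement membrane collagen chain gene, was at 335.3 ± 54.0 CPM in LER+LIG, 984.2 ± 113.6 CPM in LER and 788.7 ± 135.1 CPM in NER (SD, n = 3 each). Its partner Col4a1 was at 1039 ± 541 CPM against 2041 ± 240.3 CPM in LER, a log2 fold change of -1.51 to -0.74 with 1 library left out. The list median was -2.14 in LER+LIG replicate 2 and -0.15 and -0.35 in the others, and without that library camera gave adjusted p = 0.081, with a median of -0.30. Without LER+LIG replicate 1 the median was -0.95. Smooth muscle genes were lower in 18 of 20 by -0.50 (adjusted p = 0.00013; adjusted p = 0.48 with an estimated correlation), with the contractile gene Cnn1 at 702.5 ± 377.5 CPM against 1503 ± 343 CPM. Endothelial genes were lower in 13 of 17 by -0.36 (camera, adjusted p = 0.013, and 0.48 with an estimated correlation). Kdr, a VEGF receptor gene, was at 63.1 ± 14.0 CPM against 95.0 ± 6.3 CPM. The endothelial call was lost without LER+LIG replicate 2 at 0.095, and with the score covariate at 0.81 with a median of -0.06. By edgeR 1, 0 and 1 members passed adjusted over the list alone and 0 over all genes, while DESeq2 called Col4a2 and the endothelial list's Sox17.

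Genes of receptivity and of progesterone action also fell in LER+LIG. Receptivity and implantation regulators were lower in 20 of 31 by a median of -0.33 and progesterone-responsive genes in 14 of 21 by -0.35. camera gave adjusted p of 0.026 and 0.00095, and adjusted p = 0.48 with an estimated correlation for both. Sox17 was at 114.3 ± 21.7 CPM in LER+LIG and 280.4 ± 81.3 CPM in LER (SD, n = 3 each), and Gata2, a transcription factor gene upstream of Pgr, at 94.0 ± 13.4 CPM against 158.9 ± 3.0 CPM. Sox17 was also a member of the endothelial list and Gata2 of the mast cell list, both of which fell in this comparison. Gli1 and Ptch1, targets of Hedgehog signalling, had log2 fold changes of -2.54 ± 0.88 and -1.31 ± 0.46 (SE), and the Wnt, BMP and Hedgehog list was lower in 20 of 30 (adjusted p = 0.0077; adjusted p = 0.48 with an estimated correlation). Within the receptivity list Sgk1 and Muc1 went the other way, at 0.60 ± 0.17 and 2.54 ± 0.86 (SE). With 1 library left out Muc1 ranged from 1.51 to 2.98 and Gli1 from -3.88 to -2.09. The receptivity call was lost without LER replicate 2 at 0.062, LER+LIG replicate 1 at 0.16 and LER+LIG replicate 2 at 0.072. The progesterone list lay at 0.05 in LER+LIG replicate 1, against -1.28 and -0.95 in replicates 2 and 3. NER replicate 3, which had no ligustilide, lay at -1.10 there, at -0.59 on the signalling list and at -0.07 on the receptivity list. The progesterone median was -0.89, -0.90 and -0.20 without LER+LIG replicates 1, 2 and 3. That of the Wnt, BMP and Hedgehog list was -0.92, -0.59 and -0.25 in the same fits. With the score covariate camera gave adjusted p of 0.068 for receptivity, 0.81 for progesterone and 0.59 for Wnt, BMP and Hedgehog. The score is built from the progesterone list and marks LER+LIG replicates 2 and 3, so these losses name no cause. Of the progesterone list 2 members passed by edgeR adjusted over the list alone. DESeq2 called Sox17 and Gata2 over all genes, which are members of both the progesterone and the receptivity list.

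4 other lists fell. camera gave adjusted p of 0.0026 for immediate early genes, 0.022 for adrenergic genes, 0.033 for mast cells and 0.0020 for adipocytes, and adjusted p = 0.48 with an estimated correlation for each. Immediate early genes were lower in 18 of 22 by a median of -0.34, led by Socs3, a feedback inhibitor of cytokine signalling, at 19.5 ± 1.8 CPM in LER+LIG, 52.8 ± 9.8 CPM in LER and 43.4 ± 3.9 CPM in NER (SD, n = 3 each). Adrenergic receptor and cAMP target genes were lower in 15 of 19 by -0.42. Mast cell markers were lower in 5 of 6, with 0 counts of the tryptase gene Tpsab1 in the 3 LER+LIG libraries, while Kit, which stem cells and epithelium also express, was higher. Adipocyte markers were lower in 12 of 13 by -2.47. The adipocyte call was lost without LER replicate 1 at 0.42, where the median was -0.26, and the median was -4.67 without LER+LIG replicate 1. The immediate early median was -0.55 without LER replicate 3 and -0.71 and -0.52 without LER+LIG replicates 1 and 2. The adrenergic median was between -0.64 and -0.74 without NER replicates 2 or 3, LER replicate 3 or LER+LIG replicates 1 or 2. The immediate early call was lost without LER+LIG replicate 3 at 0.062. The mast cell call was lost without NER replicate 3 at 0.071, LER replicates 1 or 3 at 0.066 and 0.13, and LER+LIG replicates 1 or 2 at 0.47 and 0.11. Over all genes edgeR called 0 members of the 4 lists, while DESeq2 called Socs3, Tpsab1 and Gata2.

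Single genes came close to a call in 1 case. RT1-A1, a classical MHC class I gene with near-identical copies that can share reads, was at 83.7, 200.1 and 136.9 CPM in LER+LIG, 5.81 ± 1.18 CPM in LER and 13.4 ± 6.7 CPM in NER (SD, n = 3 each). Its log2 fold change against LER was 4.59 ± 0.47 (SE), with an adjusted p of 0.052 by edgeR's quasi-likelihood test. The related RT1-CE10 was at 43.8 ± 30.4 CPM against 6.04 ± 2.00 CPM, and Ctps2, a CTP synthase gene, at 94.4 ± 10.3 CPM against 48.6 ± 3.6 CPM. Downward the smallest p belonged to Socs3, Col4a2 and Sox12, with log2 fold changes of -1.44 ± 0.21, -1.55 ± 0.24 and -1.86 ± 0.30 (SE). For these 5 genes the edgeR adjusted p was 0.33. edgeR called 0 of 14232 genes, with 1777 at an unadjusted p under 0.05, 1026 higher and 751 lower, where 711.6 were expected by chance. DESeq2 called 303 genes, 151 higher and 152 lower, the 6 named here among them. In 2537 of 12142 genes (20.9%) the groups did not overlap, where chance gives 10%.

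**Figure D4:**
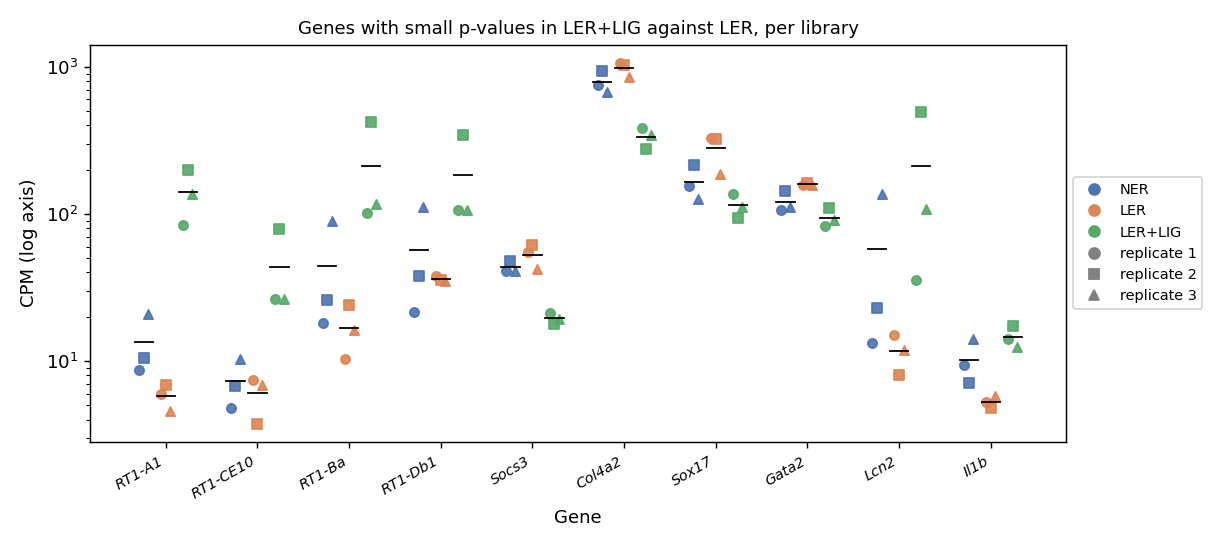
Points are single libraries in CPM on a log axis for 10 of the named genes, coloured by group and shaped by replicate number, with a black bar at the mean of the 3 libraries. RT1-A1 lies between 83.7 and 200.1 CPM in LER+LIG and at or below 20.998 CPM elsewhere, and Col4a2 lies between 277.0 and 383.6 CPM in LER+LIG and at or above 672.5 CPM elsewhere.

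The receptivity genes that were always named were not called between LER+LIG and LER by either tool, though DESeq2 called Gata2 and Sox17 of the receptivity list. Lif was at 7.80 ± 3.47 CPM in LER+LIG and 15.4 ± 4.2 CPM in LER (SD, n = 3 each), a log2 fold change of -0.98 ± 0.40 (SE) with an edgeR adjusted p of 0.38, and the groups did not overlap. Vegfa, the endothelial growth factor gene, had -0.95 ± 0.36 with an adjusted p of 0.36. Ihh, Itgb3, Itgav, Pgr, Esr1 and Hoxa11 had log2 fold changes of -1.68 ± 1.23, -0.54 ± 0.62, -0.18 ± 0.47, -0.33 ± 0.75, 0.06 ± 0.30 and -1.52 ± 0.78 (SE). Mki67, Rrm2 and Cdkn1a had -0.11 ± 0.59, -0.01 ± 0.74 and -0.04 ± 0.66 (SE). Of these genes Itgav, Pgr, Esr1, Mki67, Rrm2 and Cdkn1a changed sign with 1 LER or LER+LIG library left out, while Lif, Vegfa, Ihh, Itgb3 and Hoxa11 did not. With 1 library left out Ihh ranged from -3.84 to -1.14, Itgb3 from -1.80 to -0.15 and Hoxa11 from -1.90 to -0.63.

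Whether genes changed in LER moved back with ligustilide is the question of the third comparison. By edgeR 0 genes were called in both contrasts with opposite signs, since 0 were called in either, with 124 and 1777 at an unadjusted p under 0.05. DESeq2 gave 2 such genes, the protease genes Tmprss11b and Prss32, named after their values were seen. Both had 0 counts in NER replicates 1 and 2, in LER and in LER+LIG replicate 1, and NER replicate 3 held 20.1 and 19.3 CPM, so 1 NER library carried both calls. Across 14232 genes the log2 fold changes of both contrasts correlated at r = -0.74, and 71.5% of genes had opposite signs. Unchanged groups were simulated 50 times around the mean of all 9 libraries, with the simulated LER libraries in both contrasts. They gave r = -0.50 and 66.6%. The covariance was -0.41 observed and -0.17 simulated, a difference of -0.24. Libraries were drawn independently, so this difference cannot be told apart from the profile that NER replicate 3 shared with LER+LIG replicates 2 and 3. The 3 LER libraries were too few to be split between the contrasts.

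The authors' deposited table called genes at an unadjusted p under 0.05 with an absolute log2 fold change of at least 1. It held 46 genes up and 185 down in LER against NER, and 636 up and 467 down in LER+LIG against LER. Of the 231 genes in the first contrast, 149 went the opposite way in the second in the authors' deposited table, 121 down then up and 28 up then down. Both contrasts share the LER libraries, which favours opposite signs: the same thresholds on edgeR's unadjusted p gave 65 opposite genes among 98 and 867, and unchanged groups simulated 50 times gave a mean of 85.96 (68 to 107) among means of 383.8 and 382.7. As a share of the genes in the first contrast this was 66.3% observed and 22.4% simulated (18.5% to 26.7%). The shares rest on sets of unlike size, and the count of 65 lay under the lowest simulated count of 68. The simulation drew each gene and library independently, so it lacked the profile that NER replicate 3 shared with LER+LIG replicates 2 and 3. Neither the share nor the count tells genes that moved back from that profile. Benjamini-Hochberg adjustment of the p-values in the authors' deposited table left 0 and 493 genes under 0.05. For the 185 genes that the authors' deposited table lists as down in LER, the median log2 difference from LER was 2.34 in NER replicate 3, 0.27 and 0.32 in NER replicates 1 and 2, and -0.05, 1.48 and 2.04 in LER+LIG replicates 1 to 3. In 154 of those 185 genes NER replicates 1 and 2 both lay within a factor of 2 of LER, and the table's calls were made on the same libraries, so they are no independent evidence. The 46 genes listed as up in the authors' deposited table had medians of -1.19, -1.08 and -1.99 in the 3 NER libraries.

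LER+LIG was compared with NER to see what differed from rats that had no drug. Kap, an androgen-regulated gene that rodent uterus also expresses, was at 1143 ± 117 CPM in LER+LIG, 460.3 ± 94.5 CPM in NER and 453.2 ± 90.6 CPM in LER (SD, n = 3 each). RT1-A1 and RT1-CE10 were higher than in NER by log2 fold changes of 3.39 ± 0.44 and 2.59 ± 0.53 (SE). Socs3, Col4a2 and Ccnd2, a D-type cyclin gene, were lower by -1.16 ± 0.21, -1.23 ± 0.24 and -1.09 ± 0.24 (SE). edgeR called none of the 6, with adjusted p of 0.38 for RT1-A1 and 0.87 for the others. edgeR's quasi-likelihood test called 0 genes, with 775 at an unadjusted p under 0.05, 391 higher and 384 lower, and DESeq2 called 12, 5 higher and 7 lower, the 6 named here among them. In 1008 of 12142 genes (8.30%) the groups did not overlap, where chance gives 10%.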

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

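The score and length settings below were chosen only after the result was seen, and the other settings were fixed before the data were examined. edgeR called 0 genes in each contrast, and 0 in both with opposite signs, under TMM scaling. The count for LER+LIG against LER became 1 with upper-quartile scaling, without a filter, with the score covariate and with the length offset. In these 4 fits the gene was RT1-A1. Left-out libraries gave 0 to 1 genes there, RT1-A1 without NER replicate 3 or LER+LIG replicate 1, and Gdf7, named after its values were seen, without LER+LIG replicate 3. The DESeq2 Wald test called 2 genes for LER against NER, 303 for LER+LIG against LER, 12 for LER+LIG against NER and 2 in opposite directions, and the cause of the gap to edgeR was not tested. The score covariate gave 1 gene for LER+LIG against NER. RT1-A1 kept a log2 fold change of 3.91 to 4.83 over 19 alternatives, with adjusted p from 3.42e-20 by DESeq2 to 0.70 without LER replicate 1 by edgeR, and it was called in 7 of them.

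camera called 14 lists for LER against NER and 19 for LER+LIG against LER. With an estimated correlation and with fry both counts were 0, while fry's test for change in either direction had 2 lists for LER+LIG against LER, natural killer cells at adjusted p = 0.034 and ciliated cells at 0.0059. Left-out libraries gave 9 to 18 lists for LER against NER, with 9 without NER replicate 3, and 18 to 20 for LER+LIG against LER. The score covariate gave 12 lists for LER+LIG against LER, of which 5 were among the 19 (NRF2 targets, collagens, smooth muscle, neutrophils and mitochondrially encoded genes) and 7 were others, so 14 calls were lost. Medians there were 0.087 for interferon-stimulated genes and 0.34 for MHC class II. The score sets NER replicate 3 and LER+LIG replicates 2 and 3 apart from the other libraries, so a lost call names no cause. For LER against NER the score covariate gave 16 lists, 6 of the 14 and 10 others. camera's calls were lost for interferon-stimulated genes at adjusted p = 0.69, T cells and integrins at 0.76, and MHC class II at 0.90. The Wnt, BMP and Hedgehog call was lost at 0.90 and the erythroid call at 0.086. The medians for interferon-stimulated genes and T cells became -0.089 and -0.11. The direction of the test turned in 8 values of LER against NER. With 1 library left out the median ranged from -1.38 without NER replicate 1 to 0.075 for MHC class II antigen presentation LER vs NER, -1.07 to 0.012 for T cells and -0.79 to 0.14 for macrophages, the highest of each without NER replicate 3. It ranged from -0.37 without LER replicate 1 to 3.31 for adipocytes. For mitochondrially encoded genes LER vs NER it ranged from -0.496 without LER replicate 3 to 0.079 without NER replicate 1, and was -0.037 without LER replicate 1, where the test alone turned. With the score covariate the median was 0.070 for macrophages, and 0.15 for progesterone-responsive genes, where the test alone turned; the score is built from that list, so its turn carries no information. There 2 more medians turned while the test kept its direction, MHC class II at 0.053 and integrins at 0.076. Their cause was not tested beyond the library or term named. Under the settings other than the estimated correlation and fry, which ended all calls, 492 values of single lists kept their call and 60 lost it with the direction of the test kept. Of the values of named genes, 3051 stayed uncalled and 36 passed the threshold, and 25 of 163 pairs of gene and contrast had another sign under some setting.

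Of 9 same-numbered pairs of libraries 4 had a correlation of deviations over 0.1, with a range of -0.19 to 0.51. Differently numbered pairs ranged from -0.55 to 0.53, so these values do not settle whether replicate numbers pair the libraries. With the replicate number as a block edgeR called 0 genes in each contrast, and camera called 15 and 18 lists; the mast cell call for LER+LIG against LER was lost at adjusted p = 0.0542. Other scalings moved the median gene by at most 0.062 on the log2 scale. Alternatives planned for tables with only FPKM were not run, since counts were given. The depth, 13241537 to 15354085 counts, was not varied, so what it limits was not measured.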

Other observations

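The tests of explanations below, other than the splits of libraries and the correlation after removal of the length trend, were chosen only after the result was seen. LER+LIG also differed from NER by lists fixed in advance: camera called 17, and 0 with an estimated correlation. Collagens and crosslinking genes were lower in 21 of 23 members by a median log2 fold change of -0.73 and smooth muscle genes in 19 of 20 by -0.48, while neutrophil markers were higher in all 9 by 1.32. camera gave adjusted p of 2.24e-09, 3.66e-07 and 0.00064, and each had adjusted p = 0.49 with an estimated correlation. Relative to LER the collagen list lay at -0.15, -2.14 and -0.35 in LER+LIG and at -0.01, 0.06 and 0.09 in NER. The 3 calls held with each library left out, but without LER+LIG replicate 2 the collagen median was -0.37 at adjusted p = 0.033 and the neutrophil median 0.42 at 0.024, and without LER+LIG replicate 1 the collagen median was -1.15. camera also called both RNA quality lists higher, mitochondrially encoded genes by 0.42 at adjusted p = 0.011 and ribosomal proteins by 0.31 at 0.035. Without NER replicate 3 they were at 0.27 and 0.19. Without LER+LIG replicate 1 the ribosomal list turned, to a median of -0.25 at 0.030. Cell cycle genes of G2 and M phase had list medians of -2.05 in LER+LIG replicate 2 and -0.79 in NER replicate 3, against 0.83 in LER+LIG replicate 3. Luminal and glandular epithelium markers lay at 1.11, 1.03 and 0.93 above LER in NER replicate 3 and LER+LIG replicates 2 and 3, and at -0.74 in LER+LIG replicate 1. DESeq2 called Scgb1a1, a secretoglobin gene of secretory epithelium named after its values were seen, in LER+LIG against NER at adjusted p = 0.00080, with 7.14, 134.0 and 27.6 CPM against 1.04 to 3.62 CPM.

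NER replicate 3 shared a profile with LER+LIG replicates 2 and 3: the 200 genes with the highest weights on the first component lay 3.67, 3.31 and 3.34 above LER there, and the 200 with the lowest weights lay at -3.57, -2.98 and -3.41. A larger share of epithelial cells stays open: the epithelium list lay at 1.11, 1.03 and 0.93, within the SD of its members of 1.95, 1.38 and 1.63. The 200 genes were picked by the component itself, so a smaller rise than theirs excludes nothing. An exchange of the labels of NER replicate 3 and LER+LIG replicate 1 stays open: each correlated more with the other group, at a mean r of 0.93 and 0.922, than with its own at 0.88 and 0.84, but 0.922 is under the lowest value of 0.963 among NER replicates 1 and 2 and LER. Other values follow the labels: RT1-A1 was at 83.7 CPM in LER+LIG replicate 1 and 20.998 CPM in NER replicate 3, Kap at 1109 and 351.9 CPM, and the ratio of RT1-Ba to RT1-Bb at 1.53 and 0.41. The 7 genes that DESeq2 called lower against NER had medians of -1.89 and -0.24 there. These genes were singled out because they separate the groups as labelled. RT1-A1 was also called by edgeR against LER without LER+LIG replicate 1, at adjusted p = 0.034. The neutrophil list, fixed in advance, lay at 1.65, 2.499 and 1.66 in LER+LIG and at 0.23, 0.47 and 0.57 in NER, in order of replicate. On the interferon, MHC class II, macrophage and progesterone lists NER replicate 3 lay nearer to LER+LIG replicates 2 and 3 than LER+LIG replicate 1 did. These values point both ways, so they do not exclude an exchange. A lower progesterone response may also lie behind the shared profile. The progesterone list was at most -0.95 in NER replicate 3 and LER+LIG replicates 2 and 3, below all 10000 random lists matched on expression. Random lists do not keep genes that vary together, so such percentiles overstate how unusual a list is. LER replicate 2, in the reference group, reached percentile 99.99 on the oestrogen list with a median of 0.16. NER replicate 1 at -0.24 was also low on the progesterone list, at percentile 0.6. The oestrogen list went apart in the 3 libraries, at 1.32, -0.47 and 0.55, so a lower progesterone response cannot be told apart from other causes. No group of the design covers hormonal stage or day of collection, and both stay open.

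LER+LIG replicate 1 differed from the LER mean along gene length, with a Spearman rho across genes of -0.33. The other libraries had -0.24 to 0.15, and the -0.24 belonged to LER replicate 1, a library of LER itself. Ribosomal protein genes lay 0.95 above LER in LER+LIG replicate 1. A length-dependent yield of fragments as the whole difference is argued against: with the trend removed its mean r with LER went from 0.912 to 0.921, under the lowest value of 0.964 within LER. A part in the difference stays open, as does ligustilide, and GC content was not analysed here.

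RT1-A1 was higher in the 3 LER+LIG libraries, by 3.84, 5.09 and 4.55 on the log2 scale from LER. The highest of 5 leukocyte list medians in any of them was 2.499, and in each library it lay more than 1 below the rise of RT1-A1. RT1-A1 was singled out for its small p, so a smaller list median excludes nothing and a larger share of leukocytes stays open. A fall of the other class I RT1 genes, from which reads could have moved, was not seen against LER: the 20 other rows summed to 403.8, 811.8 and 503.9 CPM in LER+LIG and to 362.9, 202.1 and 269.1 CPM in LER. NER replicate 3 reached 563.3 CPM without ligustilide, and a rise of the whole family could hide moved reads, so these stay open. An RT1 haplotype that differs from the reference is a candidate explanation, since the ratio of RT1-Ba to RT1-Bb, whose products pair in 1 class II molecule, was at least 1.44 in LER+LIG and at most 0.91 in the other 6 libraries. The rats of 1 group could share a haplotype by descent, which would be confounded with ligustilide, and both stay open.

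The 10 splits of 6 libraries are too few for a share under 0.05. For gene counts the real value was 0 in each contrast, which any split reaches, so 10 of 10 carries no information. The highest other count was 0 for LER against NER and for LER+LIG against LER. For LER+LIG against NER it was 1309, in the split of NER replicates 1 and 2 with LER+LIG replicate 1 from the others, which points to a structure of the samples. An exchange of the labels of NER replicate 3 and LER+LIG replicate 1 would give this grouping. It also follows the first principal component, so the count does not tell an exchange from another cause of that component. By camera the other splits of the LER and NER libraries gave 15 to 24 lists, so a pass does not set these groups apart. camera called 14, the fewest, for the real LER against NER. It called 19 for LER+LIG against LER, reached by 2 of 10 with a highest other of 19, and 17 for LER+LIG against NER, with a highest other of 25. Genes called in both contrasts with opposite signs numbered 0, which 100 of 100 regroupings reach for the same reason, so nothing follows about chance. The highest other was 948.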
